A study of Homo sapiens with 2 samples.

How the data were processed

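Total RNA from 2 human melanoma cell lines was labelled with biotin and hybridised to Affymetrix Human Genome U133 Plus 2.0 arrays, with 1 array per line. IGR39 was grown from a primary cutaneous tumour described as achromic, and IGR37 from a lymph node metastasis. Per the labels' protocols, the cells were grown in DMEM with serum, the RNA was extracted with TRIzol, and labelled cRNA was made by the standard Affymetrix procedure. The series' design text also speaks of breast cell lines, which were not analysed here.

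The deposited values are log2 expression levels per probe set, made by the authors with RMA in the affy package per the submitters' processing notes. The versions are not given in the sources used here, nor is which arrays were normalised together. RMA subtracts a modelled background, makes the distributions of the arrays alike by quantile normalisation and summarises the probes of each probe set. It therefore removes any overall difference in brightness between arrays, and it compresses differences between low levels. Each array held 54675 probe sets, with values from 2.42 to 14.10 in IGR39 and from 2.39 to 14.04 in IGR37. The medians were 4.17 and 4.14.

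Probe sets were named from the platform annotation, with symbols updated through gene identifiers to a RefSeq gene table of the assembly GRCh38.p14. Of the probe sets, 62 were controls, 41091 had 1 symbol, 1801 had several and 11721 were unnamed here. The gene identifiers of 41037 probe sets matched the RefSeq table. Probe sets with several symbols or none were left out of every gene value. The gene table was used for names, chromosomes and gene order only, since the arrays carry no coordinates. XIST and Y-linked genes are not reported by name, but they were not removed from the gene counts, the correlation of the arrays or the random lists. Some members of the gene lists had no named probe set and are not reported here.

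For each of 19775 genes, the probe set with the highest mean over both arrays was kept. Counts and gene lists used the 8501 genes at or above log2 6 in the brighter of the arrays. The difference was the log2 value in IGR37 minus that in IGR39, so positive values are higher in the metastasis line, and a difference of 1 is 2-fold. With 1 array per line there is no replicate, so no test was run and no p-value or standard error is given. No difference has a replicate check, and the number of arrays limits the precision.

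As yardsticks of noise, the differences of control probe sets and the spread between probe sets of a gene were computed. For each of 27 gene lists, the median difference of the members at or above the minimum was placed among the medians of 10000 random lists. Each random list had the same size and was matched on mean expression by drawing from the 100 genes nearest in level to each member. The resulting percentile describes these arrays and is not a test of the lines. The grouping, the lists, the counts, the rule for named genes and 10 alternatives were chosen before the data were examined.

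The rule for named genes took genes with 1 symbol, at or above log2 6 in the brighter array, whose probe sets at that level all differed in 1 direction. Genes with only cross-hybridising probe sets (ending in _x_at) were left out. From these, the 15 with the largest positive and the 15 with the largest negative differences were named, with list members of large difference as examples. EGFR, TBC1D16, MITF and AXL were named whatever their value.

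The alternatives were a minimum of log2 5 or 7 or none, the mean over all probe sets of a gene, and leaving out probe sets ending in _x_at or _s_at. Further alternatives were centring the arrays on their medians, removing a lowess trend with a span of 0.3, and centring on housekeeping genes. For the lists, unmatched random lists and members at any level were also tried.

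The calculation was tested on simulated data made from 8119 of the genes with noise of SD 0.25 per array on the log2 scale. It recovered 86 of 100 genes changed by 1.5 and 100 of 100 changed by 3 at the 2-fold limit, and 33 genes without a change passed that limit. Of 200 simulated lists without a shift, 10 lay outside the central 95% of random lists. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.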

Results

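Gene expression was compared between IGR39, a line from a primary cutaneous melanoma, and IGR37, a line from a lymph node metastasis. The lines are established and were derived from the same patient, so the comparison asks how the metastatic line differs from the primary one on a shared genetic origin. The series concerns a switch of melanoma phenotype and an epigenetically regulated gene. Each line was measured on 1 array of 54675 probe sets. In IGR39, 13092 probe sets (23.9%) reached log2 6, and in IGR37 13272 (24.3%).

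Control probe sets gave the technical differences between the arrays. The 18 hybridisation spike-in probe sets differed by a median of 0.02 on the log2 scale (SD 0.08, from -0.14 to 0.21). The 24 probe sets of poly-A spike-ins, which are added to the RNA before labelling, differed by a median of 0.25 (SD 0.31, from -0.47 to 0.68), a range that holds several of the smaller list medians below. The 3' probe set of ACTB exceeded its 5' probe set by 0.75 in IGR39 and 0.83 in IGR37, and for GAPDH by 0.66 and 0.49. Among 3178 genes with at least 2 probe sets at or above the minimum, differences within a gene had a pooled SD of 0.40. These values cover the array and the probes, and no value covers the spread between cultures.

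Of 8501 genes, 973 were at least 2-fold higher in IGR37 and 808 at least 2-fold lower, while 79.0% differed by less. At the 4-fold limit, 315 genes were higher and 349 lower. In 238 of those 315 genes the level in IGR39 was under log2 6, and in 262 of the 349 the level in IGR37 was. Across genes, which are not independent replicates, the arrays correlated with Pearson's r of 0.73 and Spearman's rho of 0.74. The differences had a median of 0.07 and an SD of 1.18. Past the 2-fold limit, 672 genes had at least 2 probe sets at or above the minimum. In 660 of these (98.2%), all probe sets at that level differed in 1 direction. Dimmer probe sets were not counted. A probe set can reach the minimum through its brighter line alone, which favours a shared direction. The split into higher and lower genes depended on the scaling, with 765 genes higher and 1024 lower after centring on housekeeping genes. Averaging all probe sets of a gene gave 588 higher and 503 lower. The minimum was then applied to the averages, so genes with dim probe sets could drop out of the count.

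**Figure D1:**
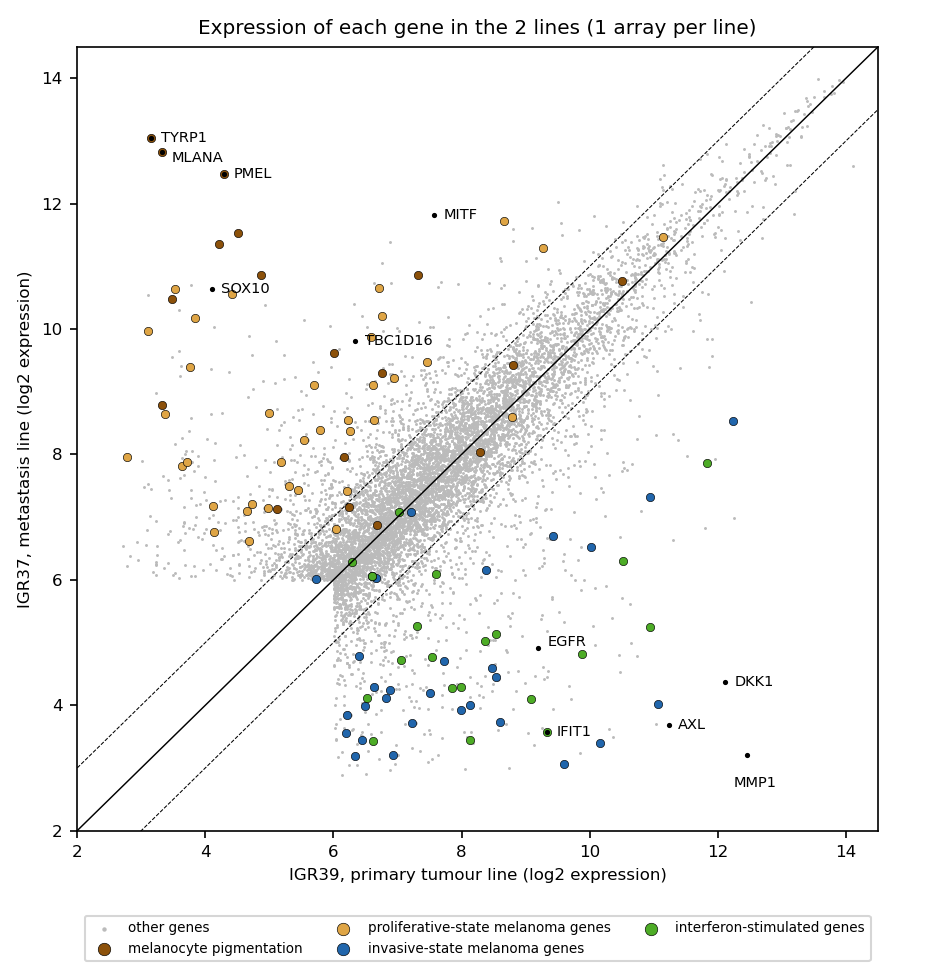
Log2 expression of 8501 genes in IGR39 (horizontal axis) and IGR37 (vertical axis), 1 point per gene, with members of 4 gene lists in colour. The solid line marks equal levels and the dashed lines a 2-fold difference. Pigmentation genes such as TYRP1 (3.15 in IGR39, 13.05 in IGR37) lie at the upper left, and MMP1 (12.45 and 3.21) at the lower right.

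Genes of melanocyte pigmentation were higher in IGR37. Of 18 measured members, 13 were at least 2-fold higher, 0 were lower and 5 lay within 2-fold. TYRP1, which encodes a melanosomal protein needed for eumelanin, stood at 3.15 in IGR39 and 13.05 in IGR37. TYR, the rate-limiting enzyme of melanin synthesis, stood at 4.22 and 11.36. The melanosome matrix gene PMEL was at 4.29 and 12.47, and MLANA stood at 3.33 and 12.83. Among those within 2-fold were AP3D1, at 8.80 and 9.43, and BLOC1S1, at 8.29 and 8.04. The list's median difference was 3.58, above all 10000 random lists.

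The transcription factors of the lineage were mostly higher as well. MITF, the regulator of melanocyte differentiation, was at 7.57 in IGR39 and 11.81 in IGR37, a difference of 4.25 with 4.97 on its other probe set at this level. SOX10, which acts upstream of MITF, was at 4.10 and 10.65, and IRF4 at 4.09 and 8.64. SOX9 went the other way, from 10.08 in IGR39 to 4.96 in IGR37. Of 10 measured members, 7 were at least 2-fold higher and 2 lower, and the median of 1.35 lay above all 10000 random lists. Counting members at any level, the median was 0.16 and lay at the 83.3rd percentile.

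Genes that mark the proliferative state of melanoma cells were higher in IGR37 too. Of 37 measured, 34 were at least 2-fold higher in IGR37 and 0 were lower, and the median of 2.62 lay above all 10000 random lists. BCL2A1, an anti-apoptotic target of MITF, was at 3.11 in IGR39 and 9.97 in IGR37. SEMA6A was at 3.76 and 9.39. GPNMB and MET were members that differed little, at 11.15 and 11.47 and at 8.79 and 8.60.

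Genes that mark the invasive state were lower in IGR37. Of 30 measured, 26 were at least 2-fold lower and 0 were higher, and the median of -3.08 lay below all 10000 random lists. LOXL2, a collagen cross-linking enzyme, was at 11.07 in IGR39 and 4.01 in IGR37. WNT5A, a ligand of non-canonical Wnt signalling, was at 8.60 and 3.74. COL13A1 and FOXF2 lay within 2-fold, with differences of 0.28 and -0.13.

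Extracellular matrix genes were lower too, with 19 of 25 measured members at least 2-fold lower and 0 higher. MMP1, the interstitial collagenase, was at 12.45 in IGR39 and 3.21 in IGR37. Collagen genes lay apart from one another: COL5A1 was at 10.47 and 4.53 and COL12A1 at 10.64 and 5.61, while COL1A1 was at 5.87 and 6.15. The median of -2.38 lay below all 10000 random lists. Of 9 integrin genes, 5 were at least 2-fold lower and 3 higher. ITGA4 was at 7.50 and 3.54 and ITGB1 at 11.91 and 9.85, against ITGB8 at 4.14 and 7.91. The integrin median was -1.55, at the 0.09th percentile, and the mean was -0.31, so the list did not move as 1 group. With members at any level the median was -0.31.

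The list of YAP-TEAD and AP-1 targets also holds factors of these pathways. Its genes were at least 2-fold lower in IGR37 for 9 of 17 members, and 0 were at least 2-fold higher. CCN1, a matricellular target of YAP, was at 10.74 in IGR39 and 4.79 in IGR37, and JUN at 8.09 and 3.98. Among the factors, YAP1 was at 8.04 and 6.95, TEAD1 at 9.35 and 9.25 and TEAD4 at 7.51 and 7.68. The median was -1.09, which is the value of YAP1, and lay below all 10000 random lists. It was -2.57 at a minimum of log2 7, -0.61 without one and -0.59 without probe sets ending in _x_at or _s_at. In the TGF-beta list, 11 of 15 members were at least 2-fold lower and 1 was higher. TGFBI was at 9.68 and 4.30, the ligand TGFB1 at 8.18 and 3.39, while TGFBR3 was higher with a difference of 1.34. The median of -1.44 lay below all 10000 random lists, and was -2.23 without probe sets ending in _x_at or _s_at.

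**Figure D2:**
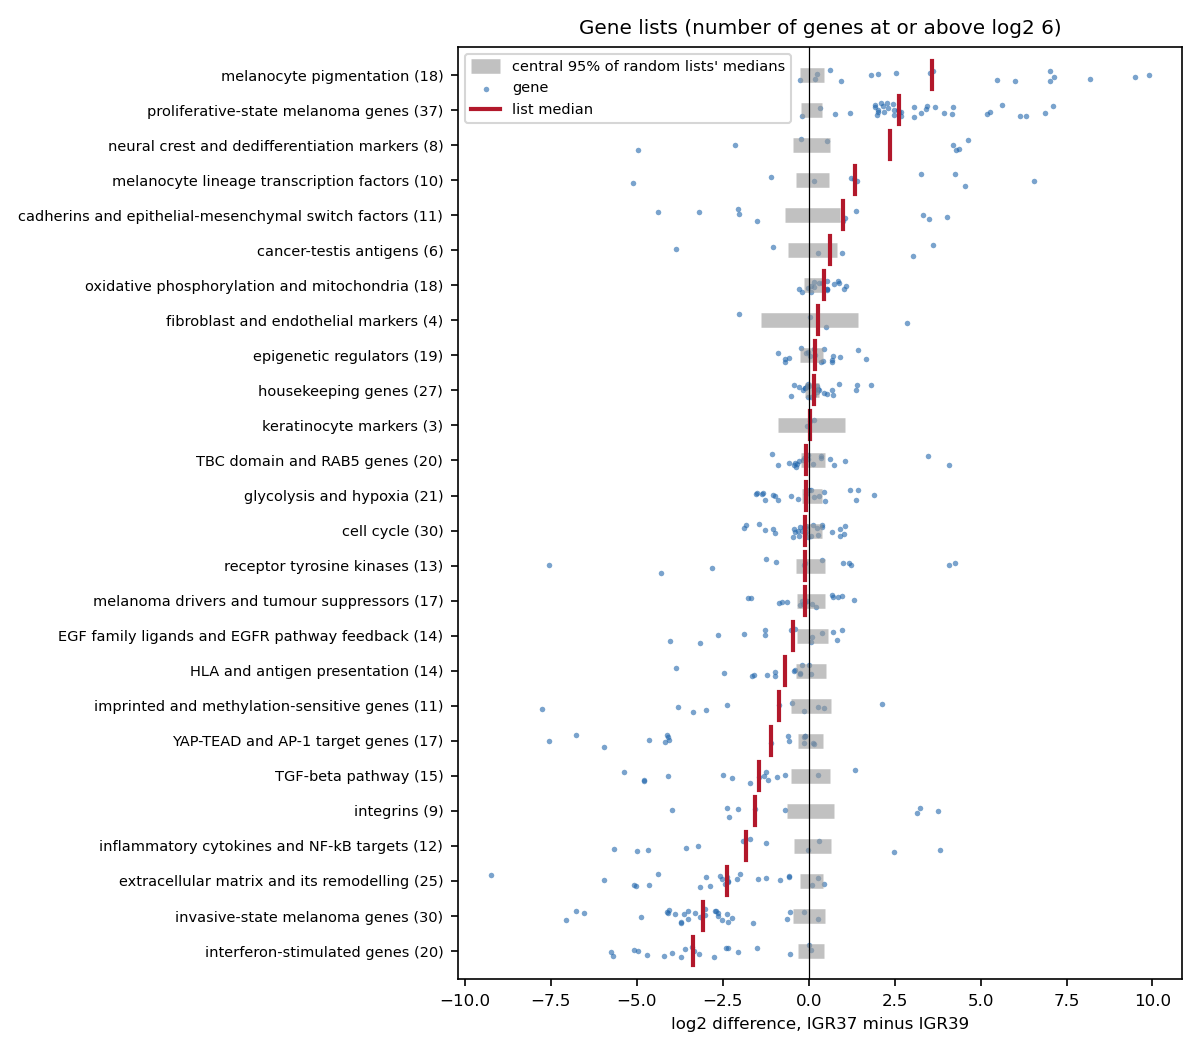
Log2 difference between the lines (IGR37 minus IGR39, horizontal axis) for the genes of 26 lists, 1 blue point per gene, with the list's median as a red bar. Grey bars span the central 95% of medians of 10000 random lists of the same size and level. The pigmentation median lies at 3.58 and that of the interferon-stimulated genes at -3.37.

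The 15 genes with the largest positive differences were led by TYRP1 (9.90), MLANA (9.50) and PMEL (8.18). They were followed by KRTAP19-1 (7.44), TYR (7.14), GPM6B (7.11), OCA2 (7.03), SLC45A2 (7.0), EDNRB (6.93) and BCL2A1 (6.86). LHFPL3-AS1 (6.73), SOX10 (6.55), CAPN3 (6.33), MBP (6.14) and TRIM63 (6.08) completed them. EDNRB is the endothelin receptor of the melanocyte lineage, OCA2 and SLC45A2 are melanosomal transporters, and MBP is a myelin gene. The 15 largest negative differences were those of MMP1 (-9.25), DKK1 (-7.75), AXL (-7.55), BASP1 (-7.33), LOXL2 (-7.05), SCG5 (-6.88) and CRIM1 (-6.76). EDIL3 (-6.68), NRP1 (-6.60), PDGFC (-6.53), CCN1 (-5.95), COL5A1 (-5.94), NR2F1 (-5.76), IFIT1 (-5.76) and HMGA2 (-5.74) followed. DKK1 is a secreted Wnt antagonist, NRP1 a co-receptor for semaphorins and VEGF, and HMGA2 a chromatin protein of embryonic and tumour cells. In all 30, the dimmer line lay below log2 6, so the differences rest on a level near background. Averaging every probe set of a gene made the difference smaller by over 1.5 times for MBP (2.21), BASP1 (-3.75), LOXL2 (-2.16), EDIL3 (-3.29) and NRP1 (-2.76).

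**Figure D3:**
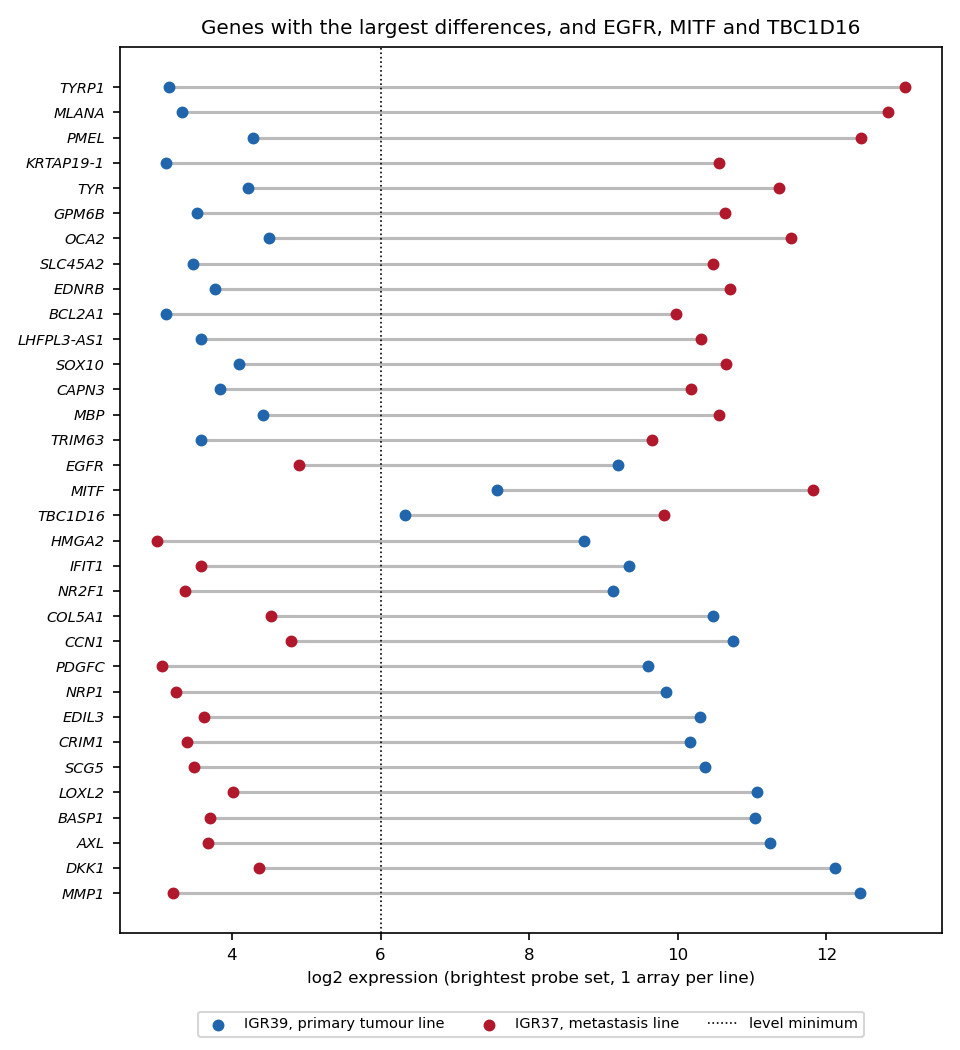
Log2 expression in IGR39 (blue) and IGR37 (red) of the 15 genes with the largest positive and the 15 with the largest negative differences, with EGFR, MITF and TBC1D16. The horizontal axis gives log2 expression, each gene has 1 line, and the dotted line marks the level minimum of log2 6. MITF is above that minimum in both lines, at 7.57 and 11.81.

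TBC1D16, a GTPase-activating gene for RAB proteins whose transcripts in melanoma the study is about, was higher in IGR37. Its brightest probe set was at 6.33 in IGR39 and 9.82 in IGR37, a difference of 3.48. The 4 probe sets that reached log2 6 differed by 1.20 to 3.80, and another was near background in both lines, at 5.14 and 5.18. The mean over all its probe sets gave 2.10. TBC1D7, a subunit of the TSC complex, was at 6.32 and 10.41. In the list of TBC domain and RAB5 genes, 3 of 20 were at least 2-fold higher, 1 was at least 2-fold lower and 16 lay within 2-fold. The median of -0.07 lay at the 14.2nd percentile, within the central 95% of random lists, while the mean was 0.31.

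EGFR was lower in IGR37, and its probe sets differed in size. The brightest was at 9.19 in IGR39 and 4.91 in IGR37, a difference of -4.29, and the 4 that reached log2 6 ranged from -4.29 to -0.52. The mean over all probe sets was -1.38, and leaving out those ending in _s_at or _x_at gave -0.52, from the brighter of the 2 remaining probe sets at this level. The other of these was at 7.44 and 4.04, a difference of -3.40. AXL, a receptor tied to the invasive state, was at 11.24 and 3.68, with -3.08 on its other probe set. KIT and ERBB3, receptors of the melanocyte lineage, were higher in IGR37, from 5.95 to 10.04 and from 3.79 to 8.06. Of 13 receptor tyrosine kinases, 4 were at least 2-fold higher and 4 at least 2-fold lower. Their median of -0.11 lay at the 23.3rd percentile, and with the mean over all probe sets it was -1.11 and at the 0.205th.

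Among EGF family ligands and feedback genes of the EGFR pathway, 6 of 14 were at least 2-fold lower in IGR37 and 0 were higher. ERRFI1, an inhibitor of EGFR induced by its signal, was at 9.86 in IGR39 and 5.84 in IGR37. The ligand TGFA was at 7.09 and 3.93, and FOSL1 at 10.52 and 7.87. SPRY2, another feedback inhibitor, was at 8.72 and 9.68. The median of -0.45 lay at the 0.83rd percentile, and without probe sets ending in _x_at or _s_at it was -0.21 and within the central 95%. It was -0.89 at a minimum of log2 7 and -0.87 with the mean over all probe sets.

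The cadherins and factors of the epithelial-mesenchymal switch divided. CDH1, which encodes E-cadherin, was at 3.07 in IGR39 and 6.56 in IGR37, and ESRP1, an epithelial splicing regulator, at 4.15 and 8.18. CDH2, which encodes N-cadherin, was at 8.90 and 5.72. The ZEB factors exchanged places, with ZEB1 at 7.48 and 3.09 and ZEB2 at 3.42 and 6.73. Of 11 members, 5 were at least 2-fold higher and 5 at least 2-fold lower. The median of 0.99 lay at the 98.4th percentile, but the mean was 0.10 and the median turned to -0.50 at a minimum of log2 5. Neural crest and dedifferentiation markers divided likewise. S100B was at 3.74 and 8.38 and ABCB5 at 3.70 and 8.06, against TMEM158 at 10.35 and 5.39. Of 8 members, 4 were at least 2-fold higher and 2 at least 2-fold lower. The median of 2.36 lay above all 10000 random lists, and at a minimum of log2 5 it was 0.52 and within the central 95%. It was 4.21 at a minimum of log2 7 and 0.29 without one.

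Interferon-stimulated genes were lower in IGR37. Of 20 members, 17 were at least 2-fold lower and 0 were higher. IFIT1 was at 9.34 in IGR39 and 3.58 in IGR37, and ISG15, a ubiquitin-like modifier, at 9.89 and 4.81. GBP1, a guanylate-binding protein gene, was at 8.13 and 3.44. MX2 and IFI6 differed by less than 0.1, at 6.29 in both lines and at 7.02 and 7.08. The median of -3.37 lay below all 10000 random lists.

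Cytokine and NF-kB target genes were at least 2-fold lower for 8 of 12 members. IL6 was at 8.70 in IGR39 and 3.69 in IGR37, CCL5 at 9.15 and 4.47, and the interleukin receptor gene IL7R at 10.46 and 4.80. TNFAIP3, a feedback inhibitor of NF-kB, and CCL20 were the 2 members at least 2-fold higher, at 6.90 and 10.73 and at 4.51 and 7.01. The median of -1.81 lay below all 10000 random lists, and it was -0.40 with members at any level and -3.21 without probe sets ending in _x_at or _s_at. In the HLA and antigen presentation list, 5 of 14 were at least 2-fold lower and 0 were higher. ERAP2, an aminopeptidase that trims antigenic peptides, was at 8.52 and 4.65, HLA-B at 11.86 and 9.39, and TAP2 at 6.34 and 6.36. The median of -0.69 lay at the 0.12th percentile. With the mean over all probe sets it was -0.46 and at the edge of the central 95%, and it was -0.39 with members at any level. Examined only after the data were seen, the 8 measured genes with HLA symbols had a median of -0.07, at the 19.4th percentile. Of these, 2 were at least 2-fold lower and 1 was higher, so the list median does not describe HLA genes as a group.

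Cell cycle genes were mostly alike, with 23 of 30 within 2-fold, 5 at least 2-fold lower and 2 at least 2-fold higher. MKI67, a marker of cycling cells, was at 9.66 in IGR39 and 7.79 in IGR37, while MCM6, a replication helicase subunit, was at 9.17 and 10.21. The median of -0.10 lay at the 5.43rd percentile, within the central 95%. Among the measured melanoma drivers and tumour suppressors, 14 of 17 lay within 2-fold. CDKN2B was at 6.27 and 4.49, CDK6 at 9.00 and 7.31 and MYC at 9.02 and 10.32. Their median was -0.12, at the 14.96th percentile.

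Of 18 genes of oxidative phosphorylation and mitochondria, 2 were at least 2-fold higher in IGR37 and 16 lay within 2-fold. ATP5F1A, a subunit of the ATP synthase, was at 11.14 in IGR39 and 12.22 in IGR37. The median of 0.46 lay at the 98.8th percentile, and without probe sets ending in _x_at or _s_at it was 0.27 and within the central 95%. In the glycolysis and hypoxia list, 6 of 21 were at least 2-fold lower and 4 at least 2-fold higher. VEGFA was at 8.50 and 6.99 and the hexokinase gene HK1 at 10.30 and 8.93, against HK2 at 5.87 and 7.29. The median of -0.09 lay at the 12.5th percentile, and with the mean over all probe sets it was -0.26 and at the 0.81st.

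Epigenetic regulators lay within 2-fold for 17 of 19 members. The exceptions were IDH1 at 9.52 in IGR39 and 10.95 in IGR37, and IDH2 at 7.43 and 9.11. The DNA methyltransferase gene DNMT1 was at 8.89 and 8.80. The median of 0.19 lay at the 75.9th percentile. Of 11 imprinted and methylation-sensitive genes, 5 were at least 2-fold lower and 1 was at least 2-fold higher. The imprinted PEG10 was at 10.48 and 6.69, SFRP1 at 8.76 and 5.40, and GSTP1 at 9.56 and 11.69. The median of -0.85 lay at the 0.435th percentile, but without probe sets ending in _x_at or _s_at it was 0.07. It was -2.98 at a minimum of log2 7 and -0.19 without one. Of 6 cancer-testis antigen genes, 2 were at least 2-fold higher and 2 at least 2-fold lower. MAGEA12 was at 4.55 and 8.15 and MAGEA10 at 8.71 and 4.85. Their median of 0.63 lay at the 92.8th percentile, and was 0.078 with the mean over all probe sets and 0.087 with members at any level. Without probe sets ending in _x_at or _s_at, too few members remained to place this list.

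Markers of other cell types were mostly at background. None of the 22 lymphocyte and macrophage markers reached log2 6 in either line, and their highest value was 5.37. Of 20 fibroblast and endothelial markers, 4 reached it. FAP was at 8.85 in IGR39 and 6.83 in IGR37, and LUM at 3.41 and 6.26. Their median of 0.27 lay at the 67.4th percentile, and was 0.029 at a minimum of log2 5 and 0.025 with members at any level. The 3 keratinocyte markers at this level lay within 2-fold, with a median of 0.03 at the 39.7th percentile. Of 27 housekeeping genes, 24 lay within 2-fold and 3 were at least 2-fold higher in IGR37, among them GUSB at 7.40 and 9.21. Their median of 0.16 lay at the 69.8th percentile.

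Of the 26 lists that could be placed, 16 lay outside the central 95% of random lists, 6 above and 10 below. For lists without a shift whose genes vary independently, 1.3 would be expected. The random lists draw genes singly, while genes of a list can differ together, so 1.3 is too low a yardstick for these lists. Some lists share members, so they are not independent of one another.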

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

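For the melanoma states and the interferon-stimulated genes, the tests were chosen only after the result was seen, except the one on interferon genes. The measurement is of 1 array per line, so each explanation concerns these 2 cultures.

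Among 13522 probe sets with no gene name here or with several, which enter no gene value, 1640 reached log2 6. Of these, 67 were at least 4-fold higher in IGR37 and 53 at least 4-fold lower, with differences up to 8.11 and down to -5.97.

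Proliferative-state and invasive-state genes differed in opposite directions, with median differences of 2.62 and -3.08. The hybridisation spike-ins differed by a median of 0.021, which decides nothing on brightness, since quantile normalisation removes an overall difference between arrays. Fibroblasts mixed into the IGR39 culture would bring their abundant transcripts. Yet 10 fibroblast markers had a median level of 4.36 in IGR39, with DCN at 4.57 and LUM at 3.41. This argues against fibroblasts as the whole cause. Of these markers, 2 reached log2 6 in IGR39, among them FAP at 8.85, against 6.83 in IGR37. Among matrix genes, COL1A2 (6.27 and 3.84) and POSTN (7.53 and 3.14) were likewise higher in IGR39. COL3A1 was low in both lines, at 4.66 and 3.83. The origin of the line, primary or metastatic, cannot be told apart from any other difference between these lines, since there was 1 line per origin, and stays open.

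Interferon-stimulated genes were lower in IGR37, with a median of -3.37. The neighbouring IFIT genes alone do not account for it, since 17 other members had a median of -3.19 and 14 of them were at least 2-fold lower. Immune cells mixed into the IGR39 culture are argued against by the markers, of which 0 reached log2 6 in IGR39. Interferon made by the IGR39 cells cannot be told apart from other causes. The highest of 18 probe sets for 18 interferon genes in IGR39 was that of IFNA7 at 3.99 (3.91 in IGR37), which is background, and little interferon mRNA could suffice.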

How the results depend on the processing

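All 10 alternatives were planned. Of 26 lists, 12 kept their sign and their side of the central 95% under every alternative run. Of these, 9 lay outside it, which were the pigmentation, proliferative-state, invasive-state, extracellular matrix, YAP-TEAD, TGF-beta, cytokine, interferon and integrin lists. A further 5 lists stayed within the central 95% with medians near 0 that changed sign or became 0. In all, 225 of 253 list values kept both sign and side, and 18 changed sign or became 0, of which 13 were within the central 95% before and after. Part of this count was fixed in advance. Centring on medians or on housekeeping genes shifts all genes alike and leaves the percentiles unchanged, and unmatched random lists leave the medians unchanged. Members at any level gave the same list values as no minimum. Of 257 values of the 33 named genes, 25 moved by over the pooled SD between probe sets of 0.40, all with another choice of probe sets. Only 32 of these genes had a value with the mean over all probe sets, where HMGA2 had none. Without probe sets ending in _x_at or _s_at 27 had one, and PMEL, CAPN3, AXL, LOXL2, CRIM1 and HMGA2 had none. The cadherin list reversed to -0.50 at a minimum of log2 5, -0.25 at 7, and -0.42 both without a minimum and with members at any level. Without a minimum, or with members at any level, the lineage factors lay at 0.16. The neural crest list was 0.52 at a minimum of 5 and without probe sets ending in _x_at or _s_at. Leaving those out also gave 0.072 for the imprinted, -0.21 for the EGF and 0.27 for the oxidative phosphorylation list. The mean over all probe sets, with the minimum applied to that mean, gave 588 genes higher and 503 lower at 2-fold, 180 and 216 at 4-fold. It gave -1.11 for receptor tyrosine kinases, -0.46 for HLA, -0.26 for glycolysis and 0.39 for oxidative phosphorylation. Averaging brings in dim probe sets, yet the receptor tyrosine kinase and glycolysis medians grew in size with it. The cause was not tested for any of these shifts. The correlation of the arrays was 0.807 at a minimum of 5, 0.640 at 7, 0.927 without one and 0.656 without those probe sets. Centring on medians and on housekeeping genes subtracted 0.07 and 0.16, while the lowess trend subtracted an amount that varies with level. For the spike-ins, only the trend's median over genes was subtracted, not the trend at their own levels, which gave -0.065. Centring on housekeeping genes put them at -0.14. Levels below about log2 6 are close to background, so differences against them are imprecise. No paired analysis was possible because each line has 1 array, and for the same reason no array could be left out.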

Other observations

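The gene families, chromosomes and gene order were examined only after the data were seen, and the tests of adjacent genes and of runs of genes were chosen after the result was seen. The tests without paralogous pairs, without strongly different genes and at 20 places apart were set before their values were seen, although chromosome medians were already known.

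The vacuolar proton pump acidifies lysosomes and melanosomes. The 15 measured genes of its subunits, whose symbols begin with ATP6V, had a median difference of 0.87, above 9998 of 10000 random lists matched on level, and 4 were at least 2-fold higher. ATP6V0D2 was at 3.99 in IGR39 and 7.64 in IGR37, and ATP6V1H at 8.31 and 9.60, while ATP6V0E1 was at 11.50 and 10.92. The ALG genes of N-glycan assembly had a median of 0.85 over 10 genes, 5 of them at least 2-fold higher, with ALG5 at 8.33 and 9.84. The CHCHD genes, most of which encode mitochondrial proteins, had a median of 0.88 over 8, 3 of them at least 2-fold higher, with CHCHD10 at 9.54 and 10.90.

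Kruppel-like transcription factors had a median of -0.98 over 10 genes, of which 5 were at least 2-fold lower in IGR37 and 1 higher. KLF4 was at 9.42 in IGR39 and 5.69 in IGR37, and KLF15 went the other way, at 5.78 and 7.19. The annexins had a median of -0.81 over 8 genes, 3 of them at least 2-fold lower, with ANXA1 at 12.26 and 6.99 and ANXA5 at 10.38 and 10.90. The lipid phosphate phosphatases (PLPP) had a median of -1.92 over 6 genes, with 5 at least 2-fold lower, and the PDZ and LIM domain genes (PDLIM) -1.20 over 6, with 3 lower and 1 higher, PDLIM3, which was at 5.15 and 8.39. The medians of the symbol stems SLC2A (-0.98), ARHGAP (-0.74) and ITGA (-2.34) were negative as well. The SLC2A stem took in SLC2A4RG (-2.24), which is no transporter gene. The 6 transporter genes alone had a median of -0.58 at the 3.01st percentile, with 2 at least 2-fold lower. Of 12 ARHGAP genes, 4 were at least 2-fold lower and 1 higher. Of 7 ITGA genes, 5 were lower and 2 higher, the latter being ITGA7 (3.24) and ITGA9 (3.15). These were the 10 of 164 symbol stems that lay at or beyond the outer 0.25% on either side. If the genes of a stem varied independently, 0.82 would be expected. Genes of a family need not vary independently, so 0.82 is too low a yardstick, and the ITGA genes overlap the integrin list above.

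Neighbouring genes differed together. In the gene order of GRCh38.p14, differences limited to 2 in size correlated at 0.233 between 8463 pairs of adjacent measured genes, against at most 0.036 in 1000 shuffled orders, so chance order is argued against. Paralogous neighbours that share probes and clusters of strongly different genes are each argued against as the whole cause, since the correlation was 0.204 without same-stem pairs and _s_at or _x_at probe sets, and 0.197 among genes less than 2-fold different. At 20 places apart it was 0.115, against at most 0.033 in shuffled orders, as broad copy number differences between the lines would give. Such differences may account for the pattern, but broad chromatin domains would give it too and no DNA measurement was analysed here.

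Chromosome medians followed the same pattern, with 9 of 23 chromosomes above and 6 below all 1000 shuffled orders. The highest median differences were 0.95 on chromosome 18 and 0.69 on chromosome 13, and the lowest were -0.50 on chromosome 10 and -0.36 on chromosome 5.

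Runs of 3 adjacent measured genes that were each at least 8-fold higher in IGR37 numbered 3, and 0 of 1000 shuffled orders had as many. Shuffling also breaks the correlation of neighbours, so this count does not show more than that correlation. The runs were MINPP1, ATAD1 and RNLS, then PMEL, CDK2 and ERBB3, then ATP10A, GABRA5 and OCA2. They were chosen after their values were seen. In the first, ATAD1 was at 3.01 in IGR39 and 7.90 in IGR37, MINPP1 at 3.23 and 6.28, and RNLS at 5.96 and 9.40. PAPSS2, which lies among them, was higher on all 3 of its probe sets (0.93, 2.83 and 4.32), but the brightest by mean stayed under log2 6 and kept it out of the run. Genes to either side of these, SHLD2 at 8.14 and 7.55 and STAMBPL1 at 7.60 and 6.10, were not higher. A single run was lower, that of IFIT2, IFIT3 and IFIT1, and 63 of 1000 shuffled orders had as many.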
